A study of Mus musculus with 2 samples.

How the data were processed

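MicroRNA sequencing of the mouse midbrain on postnatal day 0 was analysed from 2 libraries, 1 each from pup 1 and pup 3. Per the labels, each library came from total RNA of a single midbrain of the B6NCrl strain, with a size range of under 30 bases, and the animals are biological replicates 1 and 2 of 1 group. Both labels carry the same donor identifier although each names its own pup, and sex was not collected, so the spread between the libraries was read as the spread between 2 pups as labelled.

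The deposited values are raw counts per gene, and per the deposited descriptions they were made from alignments to assembly mm10 with the GENCODE M4 annotation. The aligner and the counting tool are not given in the sources used here. Each library has 1 table with 1973 genes and 3 deposited count columns, for reads on either strand, on the gene's own strand and on the opposite strand. The own-strand column was used for every main value. A further 4 rows of each table name no gene. They hold reads that were unmapped, mapped to several places, lay in no annotated gene or were ambiguous, and together they took 57.2% of the reads of pup 1 and 56.7% of those of pup 3. These rows stayed out of library sizes and tests. In each column, genes and these 4 rows add up to the same total, so a read that maps to several places is counted in no gene. Hairpins whose mature sequence is shared between loci are therefore undercounted to an unknown degree, and their levels are uncertain.

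Gene identifiers were matched without their version numbers to GENCODE M21 on GRCm38, the assembly also called mm10. A symbol was found for 1894 of the 1973 genes, and the 79 genes without one held 2 counts in all. Coordinates are those of GENCODE M21, counted from 1. Each hairpin sequence was searched for exact runs of at least 20 bases shared with another microRNA hairpin of the annotation, and 919 genes had such a run. Hairpins that overlap in position were not set against each other, so a hairpin without such a run can still lose reads. A search of the whole genome for further copies was not made.

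The own-strand counts on genes came to 2337113 in pup 1 and 3195277 in pup 3. Levels are given as CPM, own-strand counts scaled to a library total of 1000000 over genes, computed from the deposited counts, as mean ± SD over the 2 pups. Shares of a single library carry exact (Clopper-Pearson) 95% binomial intervals. A count of 0 allows up to 3 counts, or 1.28 CPM in pup 1 and 0.939 CPM in pup 3. The reads carry no molecular identifiers that were used here, so intervals and floors cover counting error only. A gene was called detected with at least 10 counts in each library.

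With 1 group there was no comparison of conditions and no test across groups. The libraries were compared with each other by Spearman and Pearson correlation of log2(CPM + 1) across detected genes, and by the ratio of pup 3 to pup 1 after TMM scaling (edgeR) with a prior count of 0.5, for the 286 genes with a mean count of at least 50. Each of these genes was given a two-sided Fisher's exact test of its counts against the rest of its library. A gene was called different with a Benjamini-Hochberg adjusted p under 0.05 and a ratio of at least 2-fold. This test compares 2 libraries and has no replicate check. The biological coefficient of variation, the spread beyond counting error, is the square root of the common dispersion that edgeR estimated with an intercept only. A chi-square over genes asked whether the libraries could be a single library deposited under both names.

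Before the data were examined, 20 lists of microRNAs were fixed, among them markers of other cell types that a dissected midbrain can hold. A list with at least 3 tested members was described by the percentile of its median log2 ratio among 10000 random lists of the same size matched on mean expression, each member being drawn from the 40 genes nearest in level. The genes named in the text were chosen by a rule fixed at the same time. It takes the 20 genes of highest mean CPM, up to 3 members of each list with the highest mean CPM, and up to 5 called genes in each direction. Genes outside the rule are marked as chosen after their values were seen.

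Hairpins of 1 strand within 10 kb of each other were treated as a cluster, and the share of the variance of log2 ratios that lay between clusters was set against 100000 permutations of the ratios within expression quintiles. Alternatives were other count minimums, either-strand counts, other scalings (DESeq2 size factors and plain CPM), other pseudocounts, fold thresholds and cluster distances, totals without the most abundant gene or without multi-locus hairpins, and each pup alone. Ratios less their linear trend on the GC content of the hairpin, clusters without the miR-200 family, and the neuron-enriched list without the hairpins of miR-9 and miR-124, were added after seeing the data.

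The calculations were tested on simulated data first. Among the 286 genes of the comparison of libraries, 97 of 98 genes changed 2.5-fold and 97 of 97 genes changed 5-fold were called in the right direction, and 0 of 91 unchanged genes were called. These counts were simulated with counting error only and no spread between animals. The 0 calls therefore give no rate of false calls between pups. The cluster test, on 130 clustered genes, gave a permutation p of 0.601 with no cluster effect and 0.001 with an effect as large as the spread between genes. Software was R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.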

Results

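MicroRNAs, small RNAs cut from hairpin precursors that repress messenger RNAs, were profiled in the midbrain of newborn mice. The midbrain is the brainstem region that holds the dopaminergic neurons of the substantia nigra and ventral tegmental area. The series has 1 group of 2 animals on postnatal day 0, pup 1 and pup 3, and no second tissue, age or treatment, so it asks which microRNA hairpins filled the newborn midbrain and how closely the animals matched. The files account for 5461825 reads of pup 1 and 7382778 reads of pup 3. Of these, 42.8% and 43.3% were counted on the own strand of a microRNA gene, 38.7% and 39.8% mapped to several places, and 14.8% and 13.2% were unmapped. All means below are over n = 2 pups with the SD.

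Among reads that map to a single place, Mir99a, a hairpin clustered with a let-7 gene in an intron of its host transcript Mir99ahg, was the most abundant at 162874 ± 16343 CPM. Reads mapping to several places outnumbered its counts in both pups (2111487 against 407663 in pup 1) and are not ranked here. Mirlet7g, of the let-7 family that accumulates as cells differentiate, followed at 71710 ± 5418 CPM. Mir487b, from the maternally expressed microRNA cluster of the imprinted Dlk1-Dio3 region, held 53490 ± 4144 CPM, and Mir335, in an intron of the paternally expressed gene Mest, held 49781 ± 9012 CPM. Mir126a, the endothelial microRNA within Egfl7, was the fifth at 33142 ± 4309 CPM.

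The 10 most abundant genes held 49.2% ± 0.653 of the own-strand counts and the 20 most abundant 63.3%. After those 5 came Mirlet7i at 26452 ± 3732 CPM, Mir137, a regulator of neuronal differentiation, at 24297 ± 3132 CPM, and Mir100 at 24264 ± 2603 CPM. Mir149 held 23628 ± 2755 CPM, Mir30e 22260 ± 1504 CPM and Mir130a 21457 ± 800 CPM. The rest of the 20 were, in falling order, Mir99b at 18626 ± 3702 CPM, Mir181c, Mir26b, Mir135b, Mir127, Mir22, Mir382, Mir369 and Mir23b at 10985 ± 394 CPM. In all, 359 of the 1973 genes were detected, with at least 10 counts in each library, and 99 reached 1000 CPM. A further 1276 genes had 0 counts in both libraries, which allows up to 1.28 CPM in pup 1 and 0.939 CPM in pup 3.

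**Figure D1:**
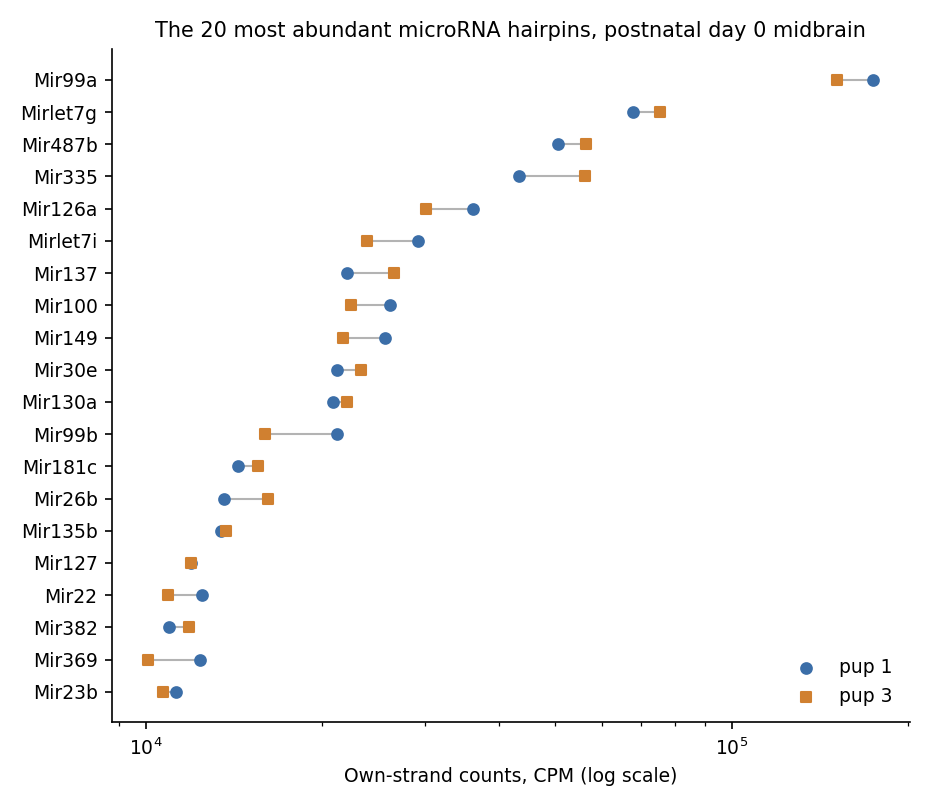
Own-strand counts of the 20 most abundant microRNA hairpins in CPM on a log scale, with pup 1 as circles, pup 3 as squares and a line joining the 2 values. Mir99a lies above all others in both pups, at 174430 CPM in pup 1 and 151317 CPM in pup 3.

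By position on GRCm38, Mir99a (ENSMUSG00000065530.1) lies on chromosome 16 from 77598936 to 77599000, in an intron of Mir99ahg. Mirlet7g (ENSMUSG00000065440.1) lies on chromosome 9 from 106178840 to 106178927, in an intron of Wdr82. Mir487b (ENSMUSG00000076219.1) lies on chromosome 12 from 109727333 to 109727414, with no host gene found on its own strand. Mir335 (ENSMUSG00000065501.1) lies on chromosome 6 from 30741299 to 30741396, in an intron of Mest. Mir126a (ENSMUSG00000065540.1) lies on chromosome 2 from 26591357 to 26591429, in an exon of an Egfl7 transcript. Mir137 (ENSMUSG00000065569.1) lies on chromosome 3 from 118433857 to 118433929, in an exon of the noncoding gene Gm26871.

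Of the 20 lists fixed before the data were examined, 7 held at least 1% of the counts. The miR-99/100 and miR-125 families led with 22.0% ± 2.33, all 6 members being detected, and Mir99a made up 73.9% of the list. The Dlk1-Dio3 cluster on chromosome 12 held 15.5% ± 0.507 with 46 of 51 members detected, led by Mir487b, Mir127 at 11949 ± 1.38 CPM and Mir382 at 11398 ± 616 CPM. The let-7 family held 12.4% ± 0.118 with 10 of 10 members detected, among them Mirlet7d at 9587 ± 161 CPM. The miR-17-92 cluster and its paralogs, expressed in dividing progenitors, held 2.42% ± 0.233 with 14 of 15 members detected. Mir17 reached 8870 ± 894 CPM, and Mir106b and Mir93, both within Mcm7, reached 4629 ± 659 and 3693 ± 226 CPM. Members that share a run with another hairpin numbered 2 of 6 in the miR-99/100 and miR-125 list and 6 of 51 in the Dlk1-Dio3 list, among them Mir487b. They numbered 5 of 10 in the let-7 list and 4 of 15 in the miR-17-92 list, so these shares and their order are uncertain.

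Neuron-enriched microRNAs held 5.05% ± 0.299 of the counts, with 14 of 17 members detected. Mir137 made up 48.1% of this list, followed by Mir153, in an intron of Ptprn2, at 9302 ± 849 CPM and Mir128-1 at 7698 ± 263 CPM. Of the 17 members 13 share a run with another hairpin, so the share of the list and the part made up by Mir137 are uncertain. The hairpins of miR-9 and miR-124, the classical neuronal microRNAs, were chosen for mention after their values were seen. Mir9-1 was counted under no gene of its own and is not among the members of this list. Mir9-3 had 389 ± 10.1 CPM and Mir9-2 1.05 ± 0.280 CPM, and Mir124a-1, Mir124a-2 and Mir124a-3 had 11.6, 3.26 and 2.17 CPM. Each of these 5 hairpins shares a run of at least 20 bases with another hairpin, and reads that map to several places are counted in no gene, so their levels are uncertain. The list of hairpins with a multi-locus mature sequence, to which they belong, held 3.76% ± 0.104, led by Mir128-1, Mir181a-1 at 4092 ± 42.7 CPM and Mir125b-1 at 3225 CPM in pup 1 and 3046 CPM in pup 3.

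MicroRNAs studied in dopaminergic neurons or changed with them held 0.848% ± 0.182, with 7 of 8 members detected. Mir7b, of the miR-7 family that represses alpha-synuclein, led with 5252 ± 1401 CPM, ahead of Mir34c at 979 ± 102 CPM and Mir7-1 at 939 ± 343 CPM. Mir34c also belongs to the list of choroid plexus and multiciliated cells, so its counts enter both shares. Mir133b, named after its values were seen, had 0 counts in pup 1 and 1 in pup 3, and it too shares a run with another hairpin. Of this list 5 of 8 members share such a run, so its share is uncertain. Glial and maturation markers had lower counted shares, which are uncertain where members share a run with another hairpin, as 2 of 3 oligodendrocyte, 3 of 4 miR-29 and 1 of 5 microglia and leukocyte members do. The oligodendrocyte list held 0.160% ± 0.00760, with Mir338 at 770 ± 30.5 CPM, Mir219a-2 at 650 ± 96.6 CPM and Mir219a-1 at 189.6 CPM in pup 1 and 176 CPM in pup 3. The miR-29 family, which rises as the brain matures, held 0.109% ± 0.0163, with Mir29a at 600.3 ± 108 CPM, Mir29c at 470 ± 53.7 CPM and Mir29b-1 at 10.3 ± 1.83 CPM. The microglia and leukocyte list held 0.0632% ± 0.00505, with Mir150 at 237 ± 35.2 CPM, Mir146 at 176 ± 12.1 CPM and Mir223 at 167 ± 3.54 CPM. With either-strand counts this list held 0.0874%, since Mir142b, named after its values were seen, had 272 CPM on its opposite strand only, above Mir150.

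Among markers of vessels, Mir126a alone held 3.31% ± 0.431 of the counts. The mural and mesenchymal list held 0.744% ± 0.00935, of which Mir143, a microRNA of smooth muscle, made up 93.9% at 6990 ± 59.9 CPM, with Mir214 at 225 ± 27.2 CPM and Mir145a at 179 ± 3.91 CPM. In this list 3 of 7 members share a run with another hairpin, so its share is uncertain. Counted markers of blood, liver and muscle were at low levels. The erythroid list held 0.00993% ± 0.00356, with Mir451a at 58.7 ± 39.2 CPM, Mir144 at 24.6 ± 6.36 CPM and Mir486 at 18.0 CPM in pup 1 and 14.1 CPM in pup 3. Mir122 of hepatocytes held 53.3 ± 7.59 CPM, or 0.00533% ± 0.000759. Striated muscle microRNAs held 0.00515% ± 0.000506, with Mir206 at 19.7 ± 0.0242 CPM, Mir208b at 14.0 ± 4.08 CPM and Mir499 at 12.1 ± 1.43 CPM. Of the 8 hairpins of this list 4 were not detected, among them Mir1a-1, Mir133a-1 and Mir133a-2, named after their values were seen, which had 0 counts and share a run with another hairpin, so their levels are uncertain.

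**Figure D2:**
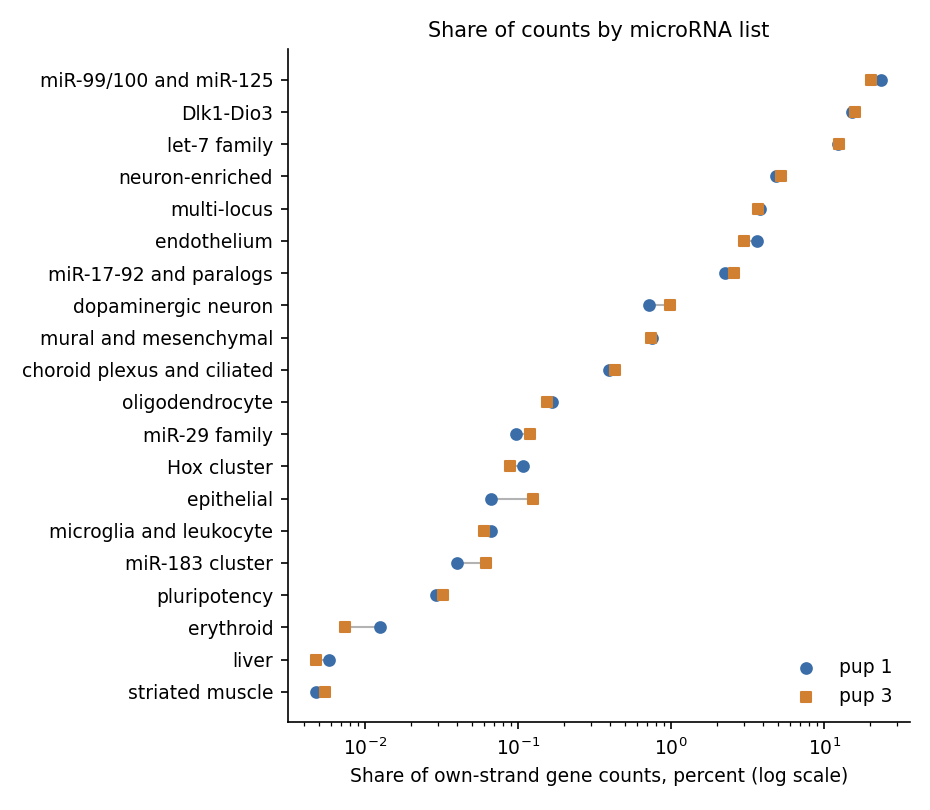
Share of own-strand gene counts held by each of the 20 microRNA lists, in percent on a log scale, with pup 1 as circles, pup 3 as squares and a line joining the 2 values. The epithelial list shows the widest relative gap, at 0.0666% in pup 1 and 0.125% in pup 3.

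The pups differed most in the miR-200 family, microRNAs that hold cells in an epithelial state. Mir429 had 53.9 CPM in pup 1 and 308 CPM in pup 3, a log2 ratio of 2.46 with a 95% counting interval of 4.57 to 6.68-fold. Mir200b, at 42 and 378 counts, had a log2 ratio of 2.65 (4.61 to 8.96-fold), and Mir200c, at 46 and 392 counts, of 2.57 (4.42 to 8.35-fold). In the other direction, Mir451a of red blood cells was 2.88-fold higher in pup 1, at 86.4 against 31.0 CPM, and Mir181a-2 was 2.81-fold higher in pup 1, at 512 against 189 CPM. These 5 of 286 tested genes passed Fisher's exact test after Benjamini-Hochberg adjustment with at least a 2-fold ratio, 3 higher in pup 3 and 2 higher in pup 1.

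Mir429 (ENSMUSG00000065427.1) and Mir200b (ENSMUSG00000065549.2) lie together on chromosome 4, from 156053905 to 156053987 and from 156055681 to 156055750, in introns of Ttll10. Both also lie within Gm13648, Mir429 in an exon and Mir200b in an intron. Mir200c (ENSMUSG00000065462.2) lies on chromosome 6 from 124718322 to 124718390, in an intron of Gm15884. The remaining members were below the count minimum and were chosen after their values were seen. Mir200a, between Mir429 and Mir200b, had 4 and 81 counts, and Mir141, beside Mir200c, had 4 and 64 counts. Mir451a (ENSMUSG00000070065.1) lies on chromosome 11 from 78073170 to 78073241. Its cluster neighbour Mir144 had a log2 ratio of 0.47 (0.973 to 2.03-fold). Mir181a-2 (ENSMUSG00000065423.1) lies on chromosome 2 from 38852735 to 38852810, and its neighbour Mir181b-2, chosen after its values were seen, had a log2 ratio of 0.02 (0.955 to 1.08-fold). Both miR-181 hairpins share a run with another hairpin, so their levels are uncertain.

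For whole lists, 4 of the 14 with at least 3 tested members had a median log2 ratio outside the central 95% of matched random lists. The epithelial list had a median of 2.46 (percentile 100), with 3 of 5 tested members called. Its share was 0.0666% of counts in pup 1 (exact 95% interval 0.0634 to 0.0700) and 0.125% in pup 3 (0.121 to 0.129), while its most abundant member, Mir203, held 588 ± 53.1 CPM with a log2 ratio of 0.13. The miR-183 cluster of sensory cells and pineal, which held 0.0508% ± 0.0150, had a median of 0.56 (percentile 99.4), with Mir182 at 0.56, Mir183 at 0.63 and Mir96 at 0.43, none reaching 2-fold. Its 3 hairpins lie in 1 genomic cluster, as do Mir429 and Mir200b of the epithelial list. Random lists were drawn gene by gene, so the percentiles of such lists may be too extreme. The miR-99/100 and miR-125 list had a median of -0.24 (percentile 1.9), and the multi-locus list of -0.11 (percentile 2.13, or 3.59 with a mean count of at least 10). The other 10 lists lay between percentiles 5.06 and 97.2. Of the 20 lists, 17 had no called member, and no count differed when adjusted over the list alone.

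**Figure D3:**
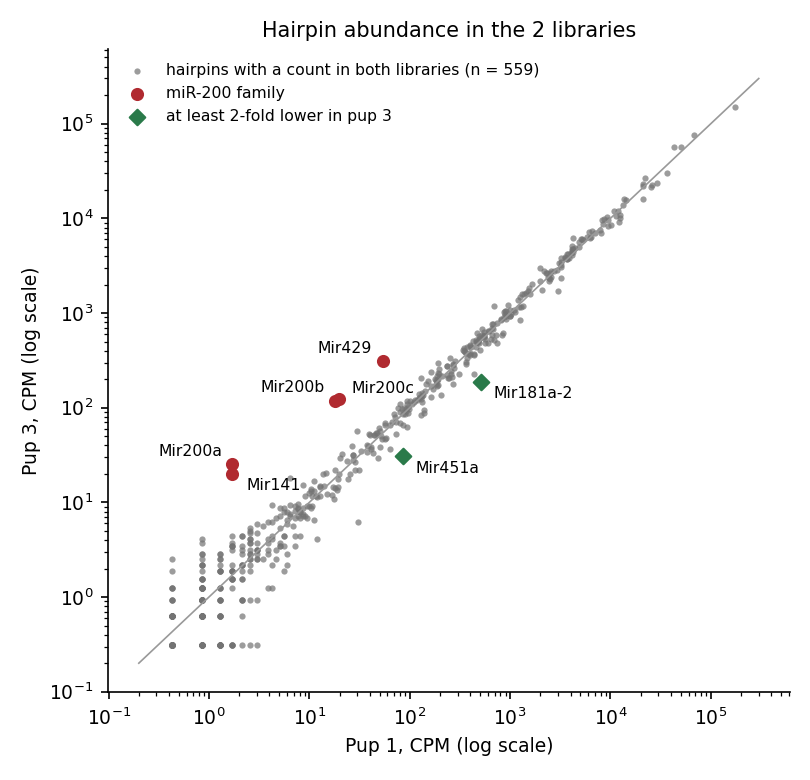
Abundance of the 559 hairpins with a count in both libraries, in CPM on log scales, pup 1 on the horizontal and pup 3 on the vertical axis, with the line of equal CPM. The 5 miR-200 family hairpins, such as Mir429 at 53.9 and 308 CPM, lie above the line, and Mir451a and Mir181a-2 below it.

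With the called genes included, the pups were close. Across the 359 detected genes Spearman's rho was 0.991 and Pearson's r 0.992, a correlation across genes, which are not independent replicates. The median absolute log2 ratio was 0.15, and 266 and 281 of the 286 tested genes lay within 1.5-fold and 2-fold. Over the 20 most abundant genes the median was 0.21, from 0.02 for Mir135b to 0.46 for Mir99b, with log2 ratios of -0.26 for Mir99a, 0.10 for Mirlet7g, 0.32 for Mir335 and -0.32 for Mir126a. The biological coefficient of variation was 0.171. The libraries differed by more than sampling noise (chi-square 33249 on 285 degrees of freedom), so they are not a single library deposited under both names. At this depth 164 genes passed the adjusted Fisher's exact test at any fold, 97 higher in pup 3 and 67 higher in pup 1, a test of these 2 libraries with no replicate check. The test used unscaled library totals and the ratios used TMM scaling, so for small ratios their directions can differ. Mir135b passed with more CPM in pup 3 (13711 against 13448) but had a log2 ratio of -0.02.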

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

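The comparisons of hairpins with and without a shared run, and the check of strand over abundant hairpins, were tests chosen after the result was seen. The overlap of opposite-strand counts with other hairpins was written down before its result.

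A group of 11 genes had reads almost only on the strand opposite to the annotated gene, a column outside the main measurement that entered the results above only for the microglia list and the either-strand alternatives. Counts opposite Gm25252 came to 10374 CPM, enough for rank 22 among all hairpins, and those opposite Gm25927 to 6928 CPM. Gm24321 had 5947 CPM, Gm24083 4680 CPM, Gm25301 2705 CPM and Gm25750 1663 CPM. Mir299b had 788 CPM, Mir497b 731 CPM, Mir142b 272 CPM, Gm24111 124.3 CPM and Gm25641 57.9 CPM, all far above the 1.28 CPM that a count of 0 allows in pup 1. These 11 genes, named after their values were seen, had at most 4 own-strand counts in either library. Opposite-strand counts made up 3.32% ± 0.112 of either-strand counts (n = 2).

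Each of the 11 genes overlaps, on the other strand, a hairpin of the GENCODE M21 annotation that was counted under no gene of its own here. They are, in the order above, Mir376a, Mirlet7e, Mir409, Mir191, Mir378a, Mir380, Mir299a, Mir497, Mir142, Mirlet7f-1 and Mir9-1. A general loss of strand in the libraries is argued against, since the median opposite-strand share over 161 abundant hairpins was 0% in both libraries and the highest 1.82%. Genes overlapping such a hairpin held 99.9% of the opposite-strand counts, so a candidate explanation is that these reads came from the overlapping hairpins, although only the overlap by position was tested. Under that hypothesis the levels given for the let-7, Dlk1-Dio3 and microglia lists leave out Mirlet7e, Mir376a, Mir409 and Mir142, among others. Those of the neuron-enriched and multi-locus lists leave out Mir9-1. No biological explanation was tested, since the series has 1 group.

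Reads mapping to several places took 39.2% ± 0.798 of all reads (n = 2) and enter no gene, and the Mir124a hairpins and Mir9-2 had at most 11.6 CPM in a brain library. Among the 17 neuron-enriched hairpins, the 13 that share a run of at least 20 bases with another hairpin had a median of 106.4 CPM, against 5840 CPM for the 4 that share none (Mir137, Mir153, Mir132 and Mir212, the last 2 named after their values were seen). An exact one-sided permutation test over all 2380 combinations gave p = 0.0105. This test contains the low hairpins that prompted it. Without the 5 Mir9 and Mir124a hairpins the medians were 842 CPM over 8 and 5840 CPM over 4 hairpins (exact one-sided permutation p = 0.141). Reads that map to several places are lost by the way of counting, so low counts of the 5 hairpins do not show that their microRNAs are scarce. How much of the low counts comes from this loss and how much from a low true level cannot be told apart, and no biological explanation was tested.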

How the results depend on the processing

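The alternatives were fixed before the data were examined, except the clusters without the miR-200 family, the ratios less their GC trend and the neuron-enriched list without miR-9 and miR-124, which were chosen after seeing the data. No result past its threshold reversed. The let-7 list, inside the central range throughout, had a median log2 ratio of -0.04, and of 0.02 with plain CPM. Requiring 1 count in each library gave 559 detected genes in place of 359. The share of the 10 most abundant genes was 47.6% with either-strand counts, 51.1% without the multi-locus list and 41.9% without Mir99a, in place of 49.2%. Without a count filter Spearman's rho was 0.911, since genes tied at or near 0 then enter. The median absolute log2 ratio was 0.175 with plain CPM and 0.171 with a mean count of at least 10, in place of 0.154. Genes differing between the libraries numbered 164 with no fold threshold, 3 with a 4-fold threshold and 11 with a mean count of at least 10, where 6 were higher in pup 3 and all 5 main calls were shared. Among these 11 the lowest ratio was that of Mir1247, named after its values were seen, at 72 counts in pup 1 and 20 in pup 3 (log2 ratio -2.33). DESeq2 size factors gave 6, plain CPM 5 and the ratios less their GC trend 5, each sharing all 5. The opposite-strand share fell to 2.34% without Gm25252. Cluster co-deviation fell to 34.1% without the miR-200 clusters (permutation p = 0.134). For these values the cause was not tested beyond what each alternative's construction shows. Leaving out each pup gave 365 to 392 detected genes, a top-10 share of 48.7% to 49.7%, and 7 lists with at least 1% of counts each time. Without Mir99a, 51 of 65 named gene levels rose by more than their SD. No paired analysis was possible because the series has 1 group. At this depth a count of 0 allows up to 1.28 CPM in pup 1 and 0.939 CPM in pup 3.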

Other observations

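The tests of counting error, of Mir203 and Mir205 and of the highest other gene, the clusters without the miR-200 family and the relation to GC content were chosen after the result was seen. The tests of Mir375 with the miR-7 and miR-183 hairpins and of genomic clusters were written down before. Mir375, Mir7-2, Mir224, Mir3078 and Mir34b were chosen for mention after their values were seen.

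MicroRNAs of the choroid plexus and of multiciliated cells held 0.413% ± 0.0259 of the counts (n = 2), with 5 of 7 members detected. Mir449a, in an intron of Cdc20b and a microRNA of multiciliated cells, led with 1842 ± 277 CPM, and Mir204, in an intron of Trpm3 and abundant in choroid plexus, had 1264 ± 121 CPM. Hairpins of the Hox clusters, which mark hindbrain and spinal cord, held 0.0983% ± 0.0131, with Mir10a at 522 ± 64.2 CPM, Mir10b at 456 ± 68.8 CPM and Mir196b at 3.94 ± 1.95 CPM. The pluripotency clusters held 0.0307% ± 0.00209, with Mir302d at 107 ± 3.55 CPM, Mir302a at 98.7 ± 3.40 CPM and Mir302b at 69.3 CPM in pup 1 and 84.8 CPM in pup 3, while Mir367 of the same cluster, named after its values were seen, had 0 counts in both libraries. The shares of both lists are uncertain, since 2 of 5 Hox and 4 of 12 pluripotency members share a run with another hairpin.

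The miR-200 family was higher in pup 3 in each of its 5 hairpins, from 5.49-fold for Mir429 to 12.8-fold for Mir200a. The value of Mir200a rests on 4 counts in pup 1 (counting interval 5.37 to 53.7-fold). Counting error is argued against by the lowest of the 5 lower counting limits, 4.20-fold. For skin or oral epithelium, Mir203, abundant there, rose by 75.05 CPM from 550.3 CPM in pup 1, with an upper counting limit of 1.18-fold. The family rose by a summed 499.01 CPM, so the rise of Mir203 was the smaller. Mir205, named after its values were seen, rose by 11.58 CPM (1.06 to 2.15-fold). This source stays open, since both rose and their levels relative to the family in such tissue were not measured here. Pituitary tissue stays open too: Mir375, abundant in endocrine cells, had an upper limit of 1.26-fold, short of the 2-fold set beforehand, but it already had 237 CPM in pup 1, so that bound would miss a small share. Of the 6 other hairpins named beforehand for pituitary, 5 had counting intervals above 1, as that prediction asked. They were Mir7b (log2 ratio 0.50), Mir7-1 (0.71) and the 3 of the miR-183 cluster (0.43 to 0.63), while Mir7-2 (0.953 to 1.10-fold) did not. Passing at any fold says little, since 97 of 286 genes did so as higher in pup 3. By size, the miR-183 list lay at percentile 99.4 of random lists, though its hairpins lie in 1 cluster. That list was fixed as one of sensory cells and pineal, and pineal tissue as a source was not tested. None of these rises reached 2-fold, but Mir7b already had 4261.2 CPM in pup 1, so a 2-fold bound would miss a small share there too. In CPM, Mir7b rose by 1980.8, Mir7-1 by 484.96 and the miR-183 hairpins by 31.32 to 102.97, against 499.01 for the summed family. Mir375 rose by 41.29 CPM and Mir7-2 by 34.04 CPM. These rises do not decide for or against pituitary, since the levels of these hairpins in pituitary were not measured here. Mir7-1 and Mir7-2 also share a run. Among genes with a mean count of at least 50 the highest log2 ratio outside the family was 0.87, for Mir224 (with a minimum of 10, Mir3078 was also called, at 15 and 58 counts and a log2 ratio of 1.41), and with 1 library per animal these sources, another cell population rich in the family and a difference between the animals cannot be told apart.

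The hypothesis that hairpins of 1 genomic cluster deviate together between pups, as a shared primary transcript would make them, was tested over 130 clustered genes. Differences between clusters held 69.1% of the variance of the log2 ratios against a permuted median of 27.0% (permutation p = 0.00047). Without the miR-200 family the share was 34.1% (permutation p = 0.134), so the result rests on the pair Mir429 and Mir200b. Some clusters moved together, such as Mir182, Mir183 and Mir96 at 0.43 to 0.63 and Mir34b and Mir34c within 0.004 of each other, and some pairs went apart, with Mir144 at 0.47 and Mir451a at -1.53, and Mir181b-2 at 0.02 and Mir181a-2 at -1.49. The simulated effect as large as the spread between genes was found at this size (permutation p = 0.001), a smaller one was not simulated, and whether the other clusters share the behaviour stays open.

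Hairpins rich in G and C tended to be lower in pup 3. Across the 286 tested genes, which are not independent replicates, the log2 ratio had a Spearman's rho of -0.20 (permutation p = 0.00093) and a Pearson's r of -0.15 (permutation p = 0.0134) with the GC content of the hairpin, and r stayed at -0.15 without the 2 genes farthest from the median. The median log2 ratio was 0.05 in the 72 genes of at most 44.1% GC and -0.06 in the 72 genes of at least 56.1% GC. A GC-dependent step in library preparation may contribute to the small differences between the pups, but subtracting the linear trend left the 5 called genes past 2-fold and did not lower the median absolute log2 ratio (0.156 against 0.154).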
